A study of Mus musculus with 14 samples.

How the data were processed

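The series holds chromatin immunoprecipitation sequencing of mouse liver, with 12 antibody libraries and 2 input libraries. Per the labels' protocols, chromatin was digested with micrococcal nuclease, immunoprecipitated with a commercial enzymatic kit, made into libraries with ligated adapters and amplified by 15 cycles of PCR. Micrococcal nuclease prefers linker DNA, so regions can follow nucleosome positions as well as enrichment. The labels give doxycycline for inducing YAP on every sample, and do not say whether WT mice also drank it, nor the sex or age of the mice. Samples were grouped by the antibody and genotype in the labels.

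Per the submitters' processing notes, the build was mm10 and the tools were Trimmomatic 0.39, BWA, SAMtools 1.7, Picard 1.126, bedtools 2.26.0 and deepTools 3.3.0. The peak caller, its threshold and the use of the inputs are not given in the sources used here. Per the labels, both replicates of an antibody and genotype share 1 list, so replicates were combined by the authors before deposit, in a manner not stated. For the histone marks, the score deposited by the authors equalled 10 times −log10 of the p-value, without decimals, in every region. The deposited −log10 p-values of these 4 lists start at 2.05, and the deposited −log10 q-values were 0 for 3986 of 5905 WT and 2378 of 6274 YAP H3K4me1 regions. Names in these lists number regions up to 10563, 64805, 16113 and 61469, in the order WT H3K4me1, WT H3K4me2, YAP H3K4me1 and YAP H3K4me2, above the number of regions listed, so the lists are parts of longer ones, by a filter that is not stated. For LSD1, every listed region has 1 width (396 bp in WT, 400 bp in YAP), and the score deposited by the authors runs from 540 to 1000, with 273 of 1718 WT and 805 of 3353 YAP entries at 1000. What the LSD1 score measures is not stated, so a higher score need not mean stronger binding. The signal column, also deposited by the authors, is an enrichment value whose exact definition is not stated; it ran from 10.6 to 97.497 for LSD1 and from 1.60 to 15.3 for the histone marks. Score and signal were used only to rank, match or filter regions within a list, never to compare genotypes. In the LSD1 lists the p-value column holds only -1 and the q-value column is partly below 0, and neither was used here.

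Overlapping or touching regions within a list were merged, which reduced LSD1 from 1718 to 1500 in WT and from 3353 to 2949 in YAP and left the histone lists as they were. Chromosomes 1 to 19, X and Y were used. Regions of different lists overlapped if they had at least 1 bp in common. Chance values are means of 100 random placements of the same regions on the same chromosome, between the first and the last gene or region there. Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, which has mm10 coordinates, with 21883 protein-coding genes on these chromosomes. The table gave neither strand nor exons. The promoter of the planned analysis therefore became a gene end, within 1 kb of either annotated boundary, exons and introns were not told apart, and the planned 5 kb upstream of a gene became 5 kb on both sides. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used, and overlaps were checked with bedtools 2.31.1 on simulated regions (2104 overlaps, 283 overlaps by at least 50% and 1034133 covered bases by both routes). In a simulated pair of LSD1 lists with 600 planted common regions, 602 were found. Of simulated gene lists without any change, 4.8% reached the 95th percentile.

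Designs were fixed before the data were examined, as descriptions without a test, because nothing measures the spread between replicates. Shares carry Wilson 95% intervals, and differences of shares carry intervals by Newcombe's method; both treat regions as independent and cover counting only. The loss of a mark at LSD1 was set beside 10000 random sets of regions of that mark matched on deciles of length, and of length and signal. LSD1 at each of 15 gene lists fixed at the same time was set beside 10000 random lists matched on 5 classes of gene length and on H3K4me2 at a gene end. H3K4me2-covered bases per gene, a measure added after the data were examined, were set beside 10000 random lists matched on 10 classes of covered bases. Percentiles describe these lists and are not p-values. All list members were found in the gene table.

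Named genes followed a rule fixed at the same time: the 10 genes with the highest-scoring YAP-only LSD1 regions at a gene end, 5 each for WT-only and common LSD1 regions and for YAP-only and WT-only regions of each mark, up to 10 genes with an LSD1 gain and a lost mark, up to 4 genes per list whose LSD1 state differed, and Kdm1a, Odc1, Yap1, Ccn1 and Ccn2. The score ranked regions, and signal broke ties, which was added because many LSD1 scores were equal. For some lists more than 4 genes with a differing LSD1 state are named, because YAP-only and WT-only genes are both given. Predicted genes with Gm or Rik symbols were skipped. Some genes that the rule or the lists would name are not reported here. Members of the fixed lists named for H3K4me2 bases, and genes named for H3K4me1 inside genes, were chosen after their values were seen.

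Alternatives were the higher-scoring 50% of each list, lists of equal size by score, a reciprocal overlap of 50%, overlap within 1 kb, joining of regions within 1 kb, autosomes only, covered bases in place of numbers, H3K4me2 regions at or off gene ends, a gene end of 2.5 kb, all 49939 annotated genes, and other distances for the gene lists. Added after the data were examined were the gene end with more H3K4me2, a q-value of at most 0.05, and, for covered bases, pseudocounts of 100 and 2000 bases and genes without flanks.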

Results

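Chromatin of mouse livers was immunoprecipitated with antibodies against H3K4me1 and H3K4me2, the mono- and dimethylated forms of lysine 4 of histone H3, and against LSD1, the demethylase encoded by Kdm1a that removes methyl groups from both forms. Livers came from wild-type C57BL/6 mice (WT) and from mice with a doxycycline-inducible YAP transgene (YAP), YAP being the transcriptional co-activator that the Hippo pathway restrains. Doxycycline was given at 50 mg/L for 10 days. Each of the 3 antibodies was used on 2 replicates per genotype, and each genotype had 1 input library, which made 14 libraries in 8 groups. The values analysed were 6 lists of enriched regions, 1 for each antibody and genotype, and each list stood for both replicates. Because of this, no spread between replicates could be computed, no p-value is given, and read depth per library is unknown. Shares of regions are given with Wilson 95% intervals, which cover counting error only. Positions are on mm10, and a gene end is either annotated boundary of a protein-coding gene with 1 kb on both sides, since the direction of transcription was not used here.

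The LSD1 lists address whether YAP expression alters where LSD1 sits in the liver, the step that the series title places at the end of a polyamine and hypusination axis. LSD1 was listed on 2949 regions in YAP livers and on 1500 in WT livers, a ratio of 1.97, and covered 1.27 Mb against 0.644 Mb. The lists had 507 regions in common. These made up 33.8% (31.5% to 36.2%) of the WT regions and 17.2% (15.9% to 18.6%) of the YAP regions, where regions placed at random on the same chromosomes gave 0.108% and 0.053%. Regions found in both genotypes had a median authors' score of 986 in the YAP list against 743 for YAP-only regions, and 825 in the WT list against 692 for WT-only regions. An LSD1 region lay at an end of 1252 of the 21883 protein-coding genes in YAP and of 670 in WT. Of these genes, 959 had it in YAP only, 377 in WT only and 293 in both, against 38.3 expected of independent lists. With both LSD1 lists limited to the same number of highest-scoring regions, 465 genes had it in YAP only. The WT list was the shorter and stayed whole, so WT-only genes numbered at least 377 in that setting. Their exact number there is not given, so 465 alone does not show an excess in YAP.

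**Figure D1:**
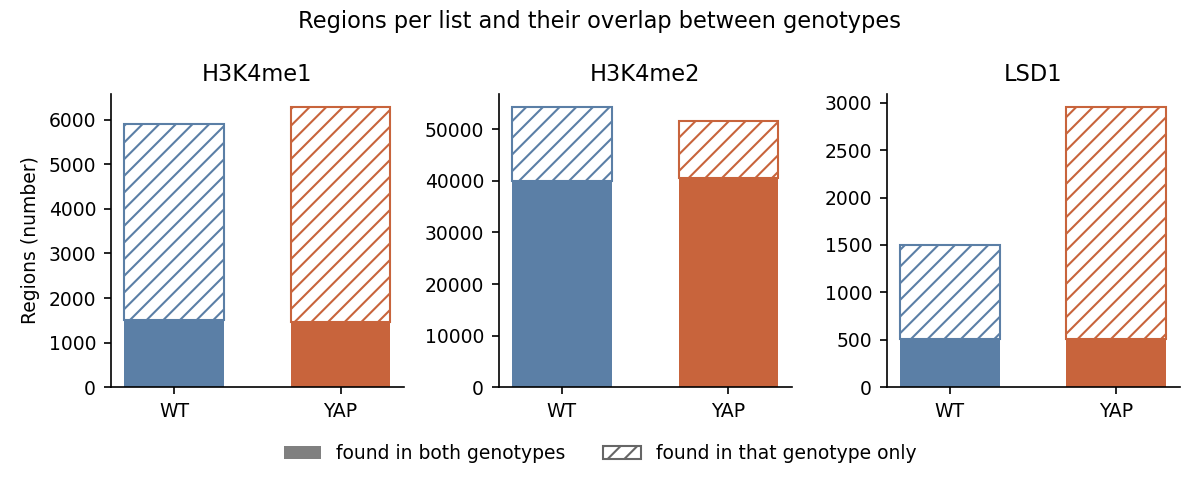
Number of listed regions (vertical axis, a separate scale for each antibody) in WT and YAP livers, split into regions found in both genotypes (filled) and in that genotype only (hatched). LSD1 had 1500 regions in WT and 2949 in YAP, of which 507 were found in both, whereas most H3K4me2 regions were found in both.

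The YAP-only LSD1 regions at gene ends that ranked highest by score and then signal, all at the highest authors' score of 1000, lay at genes of varied function. The highest signal, 90.9, was at the lower-coordinate end of Fam76b (chromosome 9, 13827067 to 13827466). It was followed by Cdk20, a cyclin-dependent kinase (71.0), Txndc12, a thioredoxin-domain protein of the endoplasmic reticulum (68.9), AU041133 (65.3), Lep, which encodes the hormone leptin (63.1), Arfip1 (61.9), Rnf187 (61.2), Hmgcs1, an enzyme of cholesterol synthesis (60.9), Shld1 (60.8) and Acap1 (60.4). All of these genes except Lep carried H3K4me2 at an end in both genotypes. The WT-only LSD1 regions that ranked highest in the same way lay at Hjurp, a histone chaperone of centromeres (signal 55.9), Tpra1 (55.1), Cycs, which encodes cytochrome c (54.7), Repin1 (53.9) and Cpb2, a carboxypeptidase made by liver (52.7). Among regions found in both lists the highest were at Ip6k2 (97.497), Fbxw7, a subunit of a ubiquitin ligase (94.8), Snx11 (94.0), Zbtb6 (78.6) and Zfp128 (77.6), as valued in the YAP list.

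Gene ends held 36.3% (34.6% to 38.1%) of the YAP regions and 38.3% (35.9% to 40.8%) of the WT regions, against 3.83% and 3.86% of random placements. The difference of YAP minus WT was -2.02 percentage points (-5.04 to 0.98), and -3.79 points (-6.89 to -0.70) with all annotated genes in place of protein-coding genes. A further 33.3% and 31.6% lay inside genes away from their ends, and 30.4% and 30.1% between genes. Of the LSD1 regions found in both genotypes, 45.0% (40.7% to 49.3%) were at gene ends, compared with 34.5% (32.7% to 36.4%) of the YAP-only and 35.0% (32.1% to 38.1%) of the WT-only regions.

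**Figure D2:**
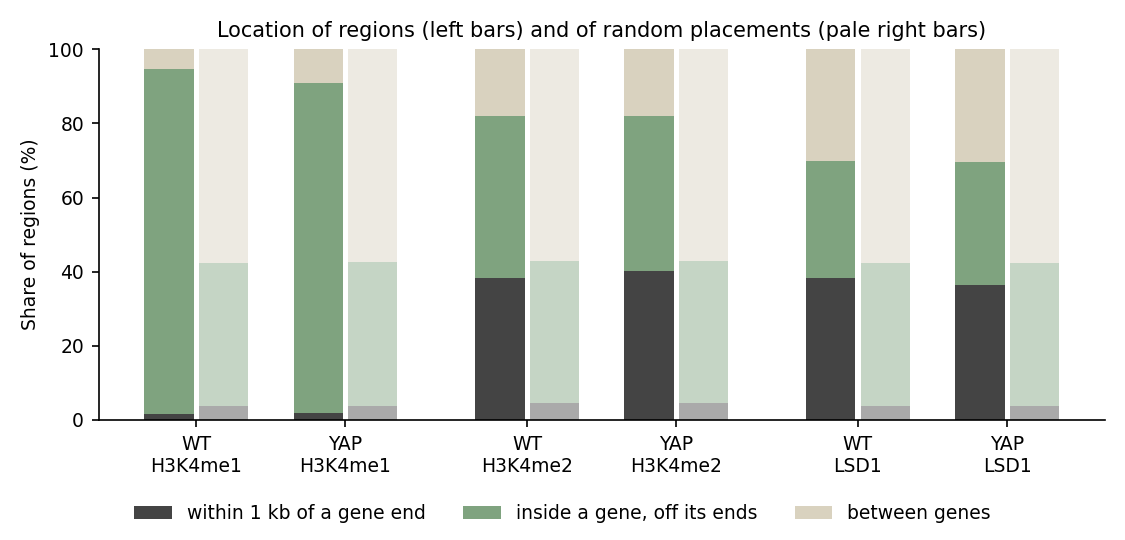
Share of regions in percent (vertical axis) at gene ends, inside genes away from their ends and between genes, for each antibody and genotype, with the mean of 100 random placements as the pale bar to the right. H3K4me1 regions lay inside genes for 93.1% in WT and 89.0% in YAP, while 36.3% to 40.2% of the H3K4me2 and LSD1 regions lay at gene ends.

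LSD1 in YAP livers only was counted in each gene or within 5 kb of it for gene groups fixed in advance. Among 30 liver metabolism genes, 8 had LSD1 in YAP only, among them Abcb11, the bile salt export pump, Asl, a urea cycle enzyme, and the bile acid synthesis enzymes Cyp27a1 and Cyp7a1, while 2 (Acly and Cyp8b1) had it in WT only and 4 in both. Random lists matched on gene length and on H3K4me2 at a gene end had 3.55 such members on average, and the count of 8 stood at percentile 98.8 of 10000 such lists. The match was on presence of H3K4me2 and not on its covered bases, and most LSD1 regions lay on H3K4me2. Percentiles of LSD1 counts may therefore reflect how much H3K4me2 a list carries. Counting all genes with LSD1 in YAP, liver metabolism had 12, against 4.90 in random lists, at percentile 99.9. Of 34 growth-restraint genes, 8 had LSD1 in YAP only, at percentile 98.2, including Bcl2l11, a pro-apoptotic factor, the anti-proliferative Btg2, the phosphatase Dusp1 and the stress-response gene Gadd45b, and Cdkn1b had it in WT only. Among 24 biliary and progenitor genes there were 5, at percentile 95.3, among them Anxa2, Notch2 and Prom1, and Clu had it in WT only. The 18 genes zoned along the liver lobule had 4 (Cyp2f2, Gls2, Sds and Slc1a2), at percentile 90.9, and the 30 hepatocyte identity genes had 5, at percentile 81.4, including Apoa2, Fgb, Foxa3 and Prox1.

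The lists closest to the title's axis stood near random lists. Of 30 YAP target genes, Amotl2, Asap1, Ccn2 and Crim1 had LSD1 in YAP only, at percentile 64.9, and Nuak2 in WT only. Of 23 genes of polyamine metabolism and hypusination, Azin1 and Azin2, which counter the antizymes that degrade ornithine decarboxylase, and the antizyme Oaz2 had it in YAP only, at percentile 68.5. Sav1, Stk4 and Tead4 did so among 18 Hippo pathway genes, at percentile 67.7, Setd1b among 15 other H3K4 enzymes, at percentile 29.97, and no gene among 15 members of LSD1 complexes, at percentile 7.46. Among 30 cell cycle genes the counts were equal, with Aurkb, Ccnd1 and Mcm4 in YAP only and Cdk1, Mcm2 and Mcm7 in WT only. The YAP-only count stood at percentile 44.7 and the WT-only count at percentile 91.9. The region counted for Mcm2 is the one at the end of Tpra1 named above. Endothelial markers had 3 (Ets1, Gata4 and Lyve1), at percentile 81.1, and the marker lists of stellate cells, macrophages and lymphocytes had none in either genotype, at percentiles 15.9, 20.6 and 25.8. Over all 334 genes of the 15 lists, 47 had LSD1 in YAP only, and 21 did with LSD1 lists of equal size. The WT-only count at equal size is not given. The order of the lists depended on the setting: with equal list sizes liver metabolism and growth restraint had 4 each and biliary genes 1, and within 50 kb hepatocyte identity had 12, growth restraint 10 and liver metabolism 8.

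The H3K4me2 lists address whether dimethylation, a substrate of LSD1, differs between the livers. H3K4me2 was listed on 54219 regions in WT and 51676 in YAP, a ratio of 0.953, and covered 52.2 Mb and 49.0 Mb. Of the WT regions 73.6% (73.3% to 74.0%) overlapped a YAP region, and 78.4% (78.1% to 78.8%) the other way round, against 3.297% and 3.44% of random placements. WT-only regions numbered 14292 and YAP-only regions 11154. These were shorter, with a median of 311 bp in WT and 298 bp in YAP compared with 792 and 758 bp for regions in both. An H3K4me2 region lay at an end of 12568 genes in WT and 12725 in YAP. It was present at 12220 genes in both, at 348 in WT only and at 505 in YAP only. The ratio of region numbers turned to 1.01 when regions of a list within 1 kb of each other were joined.

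The highest-scoring WT-only H3K4me2 regions at gene ends lay at Mup3, a major urinary protein (chromosome 4, 62085505 to 62088107, authors' score 416), Slco1a1, an organic anion transporter (chromosome 6, 141941308 to 141947471, score 344), the carboxylesterase Ces3b (score 333), the hydroxysteroid dehydrogenase Hsd3b5 (score 328) and the carboxylesterase Ces1f (score 269). Within 5 kb of Slco1a1, Ces3b, Hsd3b5 and Ces1f, H3K4me2 covered 6.88, 7.67, 3.72 and 5.02 kb in WT and no base was listed in YAP, whereas at Mup3 it covered 7.14 kb in WT and 2.09 kb in YAP. Mup3, Slco1a1 and Hsd3b5 are expressed more in livers of male mice, and the sex of the mice is not given. Most of these genes have close relatives in the mouse genome, among which aligned reads can be divided. The highest-scoring YAP-only regions lay at Kifc3, a kinesin (chromosome 8, 95199058 to 95203215, score 282), Relb, a subunit of NF-kappa B (score 272), the secreted guidance factor Sema3c (score 267), Spink1, a secreted trypsin inhibitor (chromosome 18, 43734168 to 43738341, score 262), and Olfml3 (score 243). H3K4me2 covered 5.92 kb at Spink1 in YAP and 2.04 kb at Sema3c, where none was listed in WT, and Relb had another H3K4me2 region at an end in WT.

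H3K4me2 covered fewer bases in YAP livers at hepatocyte genes and more at YAP target and biliary genes. Chromatin was from bulk liver, so these values do not tell in which cell types H3K4me2 differed, nor whether the mix of cell types did. Covered bases were summed over each gene with 5 kb on both sides and compared as log2 of YAP over WT after adding 500 bases to both. The median over the 14912 genes with any covered base was -0.06. Of 30 hepatocyte identity genes, 28 had fewer covered bases in YAP and 2 had more (Trf and Hp), with a median of -0.34 at percentile 0.02 of 10000 random lists matched on covered bases, but -0.22 at percentile 4.84 without the flanks. The urea cycle genes Cps1 and Ass1 went from 15.5 to 7.75 kb and from 8.54 to 3.79 kb, and Nr1h4, the bile acid receptor, from 20.8 to 11.8 kb. Of the 29 liver metabolism genes with covered bases, 24 had fewer in YAP, with a median of -0.42, below all of the random lists. At the drug-metabolising cytochromes Cyp2e1 and Cyp2c29, 8.14 and 5.37 kb were covered in WT and no base was listed in YAP, and Cyp7a1 went from 6.92 to 2.67 kb. Genes zoned along the lobule had a median of -0.27, at percentile 0.69, with fewer bases at 14 of 18, and stood at percentile 6.43 among the higher-scoring 50% of regions. These included the pericentral genes Cyp1a2 (3.36 to 0.38 kb) and Oat (4.15 to 1.46 kb) and the periportal genes Sds (1.55 kb to none listed) and Cyp2f2 (5.68 to 2.68 kb).

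All 30 YAP target genes carried covered bases, and 24 had more of them in YAP, with a median of 0.27 above all of the random lists. Ccn2 went from 0.53 to 3.49 kb, Myof from 0.81 to 3.38 kb and Foxf2 from 0.45 to 2.22 kb, and Ankrd1 had 1.03 kb in YAP and none listed in WT. Amotl1 (2.32 to 0.45 kb) and Rbms3 (3.78 to 1.68 kb) went the other way. Of the 19 biliary and progenitor genes with covered bases, 11 had more in YAP, with a median of 0.26 at percentile 99.99 (0.089 at percentile 98.6 without the flanks), including Spp1, which encodes osteopontin (0.62 to 3.75 kb), Prom1 (1.67 to 3.97 kb) and Anxa2 (1.72 to 4.09 kb). Krt7 and Krt19, keratins of bile duct cells, had none in either list. All 11 macrophage and Kupffer cell genes with covered bases had more in YAP, with a median of 1.149 above all of the random lists. They included Adgre1 (none listed in WT, 1.36 kb in YAP) and Spi1 (0.75 to 3.38 kb). However, 6 of the 11 had no base listed in WT. These were counted only because of their bases in YAP, so their direction was fixed in advance. The list median also depends on the bases added (2.13 with 100 and 0.43 with 2000). Among the higher-scoring 50% of regions only 5 genes of this list had covered bases, with a median of 0.010 at percentile 65.45. Stellate cell and fibroblast genes had fewer at 9 of 12 (median -0.29, percentile 2.52), endothelial genes at 9 of 17 (median -0.04, percentile 41.6), and lymphocyte genes at 4 of 8 (median -0.06, percentile 36.9), although Ptprc, a gene of all leukocytes, had 2.70 kb in YAP and none listed in WT. Among the higher-scoring 50% of regions the stellate median was 0.039 (percentile 63.5) and the endothelial median -0.71 (percentile 0.26). Only 6 stellate and 9 endothelial genes had covered bases there.

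The remaining lists differed little. Cell cycle genes had a median of 0.03 (percentile 97.7), with 16 of 30 above 0, among them Mybl2 (0.18 to 2.07 kb) and Ccnb2 (0.53 to 2.65 kb), and growth-restraint genes a median of 0.02 (percentile 98.7), with Cdkn1c going from 0.23 to 2.13 kb and Nf1 from 3.86 to 9.62 kb. Among the higher-scoring 50% of regions these lists stood at percentiles 94.92 and 94.85. The rise at Nf1 lay around Evi2, another gene inside its bounds. With 5 kb on both sides, Evi2 had no base listed in WT and 6.10 kb in YAP. Polyamine and hypusination genes had a median of -0.08 (percentile 36.7), although Arg2, a mitochondrial arginase, had 1.81 kb in YAP and none listed in WT. Medians were -0.12 for LSD1 complex genes (percentile 23.9), -0.12 for other H3K4 enzymes (percentile 28.5) and -0.07 for the Hippo pathway (percentile 56.4).

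**Figure D3:**
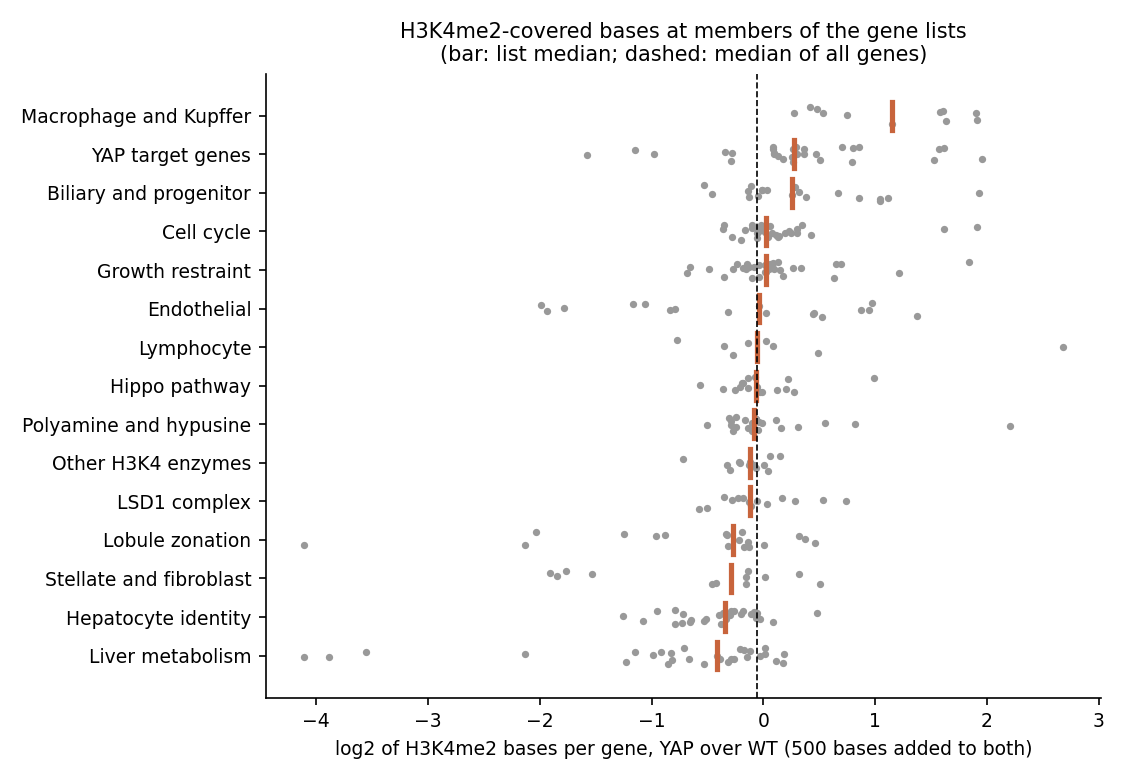
Each point is 1 gene of a list fixed in advance, placed by log2 of the H3K4me2-covered bases in YAP over WT with 500 bases added to both (horizontal axis), among genes with any covered base; bars are list medians and the dashed line is the median of all genes at -0.06. Liver metabolism (-0.42) and hepatocyte identity (-0.34) lie to the left, and YAP target genes (0.27), biliary genes (0.26) and macrophage genes (1.149) to the right.

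Of the genes fixed for report whatever they showed, Ccn2, a secreted matricellular protein and YAP target, had the clearest difference. A YAP-only LSD1 region lay at its lower-coordinate end (chromosome 10, 24595098 to 24595497; gene 24595442 to 24598683). It overlapped an H3K4me2 region that was listed in both genotypes, and a further H3K4me2 region over the gene (24595506 to 24598696) was listed in YAP only. Ccn1, a related YAP target, had 5.46 kb of H3K4me2 in WT and 6.71 kb in YAP with no LSD1 region. Kdm1a itself had 2.57 and 1.57 kb, Odc1, which encodes ornithine decarboxylase, 2.95 and 2.92 kb, and Yap1 4.06 and 3.89 kb. None of these 4 genes had an LSD1 region in either list, and Yap1 held 2 H3K4me1 regions in WT and 1 in YAP.

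H3K4me1 was listed on 6274 regions in YAP and 5905 in WT, a ratio of 1.06, covering 2.30 and 2.06 Mb. By the rule of 1 bp the lists overlapped little, with 25.5% (24.4% to 26.6%) of the WT regions found in YAP and 23.5% (22.4% to 24.5%) of the YAP regions found in WT, against 0.192% and 0.178% of random placements. The share of WT regions absent in YAP was 74.5% by this rule. It was 55.6% when overlap within 1 kb counted and 87.5% with a reciprocal overlap of 50%. The regions lay inside genes and away from their ends for 93.1% (92.5% to 93.7%) in WT and 89.0% (88.2% to 89.8%) in YAP, and at gene ends for only 1.66% and 2.01%, below the 3.66% and 3.68% of random placements. At least 1 region fell in 1846 genes in WT and 2143 in YAP, 1255 of them in both. Enrichment was weak in these lists, since 1 WT region and 102 YAP regions had a q-value of at most 0.05 in the deposited columns, compared with 97.0% and 96.3% of the H3K4me2 regions.

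The first genes named for H3K4me1 were chosen after their values were seen, among genes that held many regions. Srgap2 (chromosome 1, 131285251 to 131527531), held 4 regions in WT and 31 in YAP, the receptor phosphatase Ptprj 8 and 25, Zfp608 5 and 17, and Magi1 and Rapgef2 4 and 16 each. In the other direction, Zfand3 held 31 and 19, Nr3c1, the glucocorticoid receptor, 22 and 11, and the copper transporter Slc31a1 11 and 1. By the fixed rule, the highest-scoring YAP-only H3K4me1 regions at gene ends lay at Zfp281 and Utp3 (authors' score 78 each), Ap4s1 (71), Dok2 (68) and Tgoln1 (65). The WT-only ones lay at Mroh2a (67), Gsap (59), Hjurp (55), Adh6b (52) and Lcmt2 (52). Mroh2a had another H3K4me1 region at an end in YAP, and the regions at Mroh2a and Hjurp were no longer WT-only when regions within 1 kb were joined. Of the fixed lists, YAP target genes held 18 regions in WT and 35 in YAP, of which Dlc1 held 12 and 6 and Asap1 3 and 11, Hippo pathway genes 14 and 26, of which Vgll4 held 5 and 11, and hepatocyte identity genes 18 and 13, of which Nr1h4 held 10 and 1, while the number of hepatocyte identity genes with a region was 3 in WT and 7 in YAP. These counts were not set beside random lists.

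LSD1 and both marks were then joined, to ask whether the marks that LSD1 removes were lost where LSD1 was listed. LSD1 regions lay on H3K4me2 for 64.9% (63.2% to 66.6%) in YAP and 72.3% (70.0% to 74.5%) in WT, against 2.76% and 2.90% of random placements. They lay on H3K4me1 for 0.949% and 0.733%, against 0.194% and 0.191%. The shares cannot be compared directly between marks, because the weakly enriched H3K4me1 lists covered 2.30 Mb in YAP and 2.06 Mb in WT. H3K4me2 covered 49.0 and 52.2 Mb. H3K4me2 was lost least often where LSD1 was listed. Of 1708 WT H3K4me2 regions at YAP-only LSD1 regions, 8.55% (7.31% to 9.97%) were absent in YAP, compared with 7.73% (5.58% to 10.6%) of 440 at LSD1 regions of both genotypes, 11.5% (9.51% to 13.9%) of 797 at WT-only LSD1 regions and 27.3% (26.9% to 27.7%) of 51274 without LSD1. The difference between YAP-only LSD1 and no LSD1 was -18.8 percentage points (-20.1 to -17.3), but -7.50 among the higher-scoring 50% of regions, -7.22 at gene ends, and -5.96 (-11.8 to 0.076) with a reciprocal overlap of 50%, an interval that includes 0. The 50% rule also decided which H3K4me2 regions counted as lying at LSD1. Long H3K4me2 regions over an LSD1 region then counted as without LSD1, so -5.96 compares other classes of regions than -18.8 does. Random sets of WT H3K4me2 regions matched on length lost 16.1% on average, and sets matched on length and signal 10.0%, with the observed loss at percentile 0.74 of 10000 of the latter, and the loss at LSD1 regions of both genotypes at percentile 2.10, with a matched mean of 10.1%. The loss at WT-only LSD1 regions stood at percentile 76.9, with a matched mean of 10.9%. Appearance of H3K4me2 in YAP was seen at 10.8% (9.48% to 12.4%) of 1770 YAP regions at YAP-only LSD1 regions, 5.50% (3.69% to 8.12%) of 418 at LSD1 regions of both genotypes, 4.43% (3.15% to 6.18%) of 723 at WT-only LSD1 regions and 22.4% (22.001% to 22.741%) of 48755 without LSD1. Sets matched on length and signal gave 9.82% for the YAP-only class, with the observed share at percentile 95.4. They gave 9.15% for LSD1 regions of both genotypes, where the observed share stood at percentile 0.12. For the WT-only class they gave 9.51%, and the observed share was below that of every set. H3K4me1 could not be compared in this way, because only 16 WT H3K4me1 regions met a YAP-only LSD1 region; 75.0% (50.5% to 89.8%) of them were absent in YAP, against 74.5% (73.3% to 75.6%) without LSD1.

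**Figure D4:**
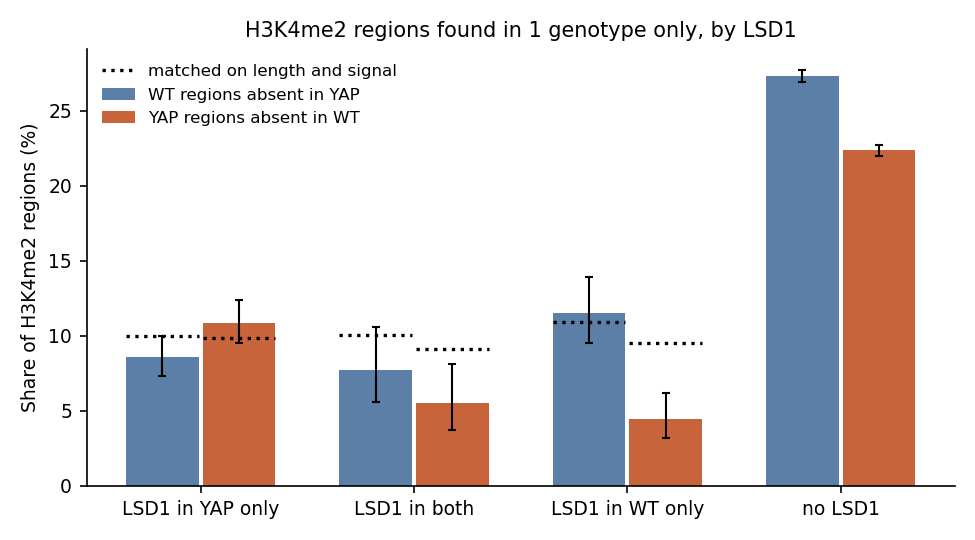
Share of H3K4me2 regions in percent (vertical axis) that were listed in WT and absent in YAP (blue) or listed in YAP and absent in WT (orange), by the LSD1 class of the place; error bars are Wilson 95% intervals and dotted lines are means of random H3K4me2 sets matched on length and signal. Regions without LSD1 had the highest bars, 27.3% and 22.4%.

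At the level of genes, an LSD1 gain and a loss of H3K4me2 rarely coincided. Among 12568 genes with H3K4me2 at an end in WT, 940 had LSD1 at an end in YAP only and 348 lost H3K4me2. In all, 5 genes did both, where independent lists would share 26.0, a value that takes no account of H3K4me2 strength. LSD1 and H3K4me2 could lie at opposite ends of a gene. Taken only at the end with more H3K4me2, 4 genes did both. The count was 2 with lists of equal size and 17 over all annotated genes. No independent value is given for these alternative settings. Loss of both LSD1 and H3K4me2 was also rare, at 2 genes against 10.3. Among 12725 genes with H3K4me2 at an end in YAP, 8 gained both LSD1 and H3K4me2, against 37.4. For H3K4me1, 8 of 91 genes with a region at an end in WT gained LSD1 and lost the region, against 9.10. By the fixed rule the genes that gained LSD1 and lost either mark were, from the highest LSD1 score, Chmp1b (1000), Plvap, an endothelial membrane protein (932), Sowahb (876), Gmps, an enzyme of purine synthesis (778), Hs3st3b1 (758), Ndufaf5 (647), Lcmt2 (645), Slc25a46 (601), Pcdh12 (584) and Id1, an inhibitor of DNA binding (541). The lost mark was H3K4me2 at Plvap, Slc25a46 and Pcdh12 and H3K4me1 at the other genes named by this rule. These losses refer to gene ends only. Within 5 kb of the gene, H3K4me2 covered 2.645 kb in WT and 0.995 kb in YAP at Plvap. It covered 2.33 and 2.03 kb at Slc25a46, and 2.39 and 2.41 kb at Pcdh12, where it was thus not lower in YAP.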

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

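No paired analysis was possible because 1 list per antibody and genotype covers both replicates, and for the same reason no replicate could be left out. Settings with a q-value limit, with the gene end that has more H3K4me2, and all settings for H3K4me2 bases of gene lists were chosen after seeing the data. Of the alternative values for the comparisons' main results, 36 of 86 lay outside the interval or the 1.5-fold range of the reported value, 4 reversed and 46 did neither. Of the alternative medians of gene lists, 8 were weaker, 7 stronger and 90 the same. With autosomes only no result left its range. Ratios of region numbers with the higher-scoring 50%, and the LSD1 ratio by covered bases of regions of fixed width, repeat the reported ratio by construction and are no support for it. The reversals concerned the H3K4me2 ratio, which became 1.01 with regions within 1 kb joined, and the H3K4me1 loss at YAP-only LSD1 minus that without LSD1, reported as 0.53 percentage points, which became -11.9 with the higher-scoring 50%, -13.5 with regions joined and -15.6 with equal list sizes; it rests on 16 regions.

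With the higher-scoring 50% of each list, 78.6% of WT H3K4me1 and 16.1% of WT H3K4me2 regions were absent in YAP, 53.3% of YAP LSD1 regions lay on H3K4me2 and 0.329% on H3K4me1, the H3K4me2 loss difference was -7.50 points, and 519 genes had LSD1 at an end in YAP only. With regions within 1 kb joined, absent shares were 72.2% and 19.99%, and the loss difference was -16.8 points. With equal list sizes, 24.4% of YAP LSD1 regions were also in WT, absent shares were 75.6% and 24.5%, the loss difference was -16.2 points, 465 genes had LSD1 in YAP only, 2 genes gained LSD1 and lost H3K4me2, and 21 list genes had LSD1 in YAP only. WT-only counts of genes are not given for this setting. With reciprocal overlap of 50%, 15.6% of YAP LSD1 regions were in WT, absent shares were 87.5% and 47.2%, LSD1 lay on H3K4me2 for 11.97% and on H3K4me1 for 0.203%, and the loss difference was -5.96 points (-11.8 to 0.076). The drop to 11.97% follows from construction, since LSD1 regions of fixed width cannot fill 50% of a long H3K4me2 region. For the same reason the loss difference of -5.96 points rests on changed classes, with long H3K4me2 regions counted as without LSD1. Counting overlap within 1 kb gave 19.3%, 55.6%, 12.6%, 72.6% and 4.00% for the same quantities, and -8.33 points. The loss difference was -7.22 points for H3K4me2 regions at gene ends and -20.5 points off them. Genes that gained LSD1 and lost H3K4me2 numbered 3 with a gene end of 2.5 kb and 17 over all annotated genes. The LSD1 share at gene ends, YAP minus WT, was -3.79 points (-6.89 to -0.70) over all annotated genes, the only setting whose interval excluded 0. List genes with LSD1 in YAP only numbered 18 at gene ends and 74 within 50 kb. With q of at most 0.05, the H3K4me1 ratio became 102 from 1 WT region, and that WT region was absent in YAP (100%). The H3K4me1 loss at gene ends gave no value for want of regions, and it was not run with the limit on q. The cause of the other changes was not tested.

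For H3K4me2 bases, YAP target, biliary and liver metabolism genes stayed outside the central 95% of random lists in all 7 settings, although the biliary median was 0.089 without flanks. With the higher-scoring 50%, lobule zonation (-0.17), cell cycle (0.030), growth restraint (0.016) and macrophage genes (0.010) came inside it. Endothelial genes (-0.71) left it in that setting, and the stellate median was 0.039 (percentile 63.5). These values rest on fewer genes, as 5 macrophage, 9 endothelial and 6 stellate genes had covered bases there. With regions joined, cell cycle (0.023) and growth restraint (-0.010) came inside, and stellate (-0.37) and endothelial genes (-0.40) left. Without flanks, hepatocyte identity (-0.22, percentile 4.84) and cell cycle (0.022) came inside and stellate genes (-0.46) left. Stellate genes also left with equal list sizes (-0.29) and with q of at most 0.05 (-0.29), as did endothelial genes with the latter (-0.26). The macrophage median was 2.13 with 100 bases added and 0.43 with 2000. The median of all genes ran from -0.07 to -0.04. Of 50 named entries, 44 kept their class of region with the higher-scoring 50%, 45 with equal sizes, 47 with overlap within 1 kb, 46 with joining, and 50 in the remaining 2 settings.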

Other observations

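Tests below that were chosen only after the result was seen were the share of WT LSD1 regions in YAP, the bases at Y-linked genes, and the ratio of H3K4me2 ratios around LSD1.

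Outside the fixed lists, genes among those with the longest losses of H3K4me2-covered bases are given first, all chosen after their values were seen. Ttc39c went from 39.9 kb in WT to 8.51 kb in YAP, Adk, adenosine kinase, from 37.5 to 20.4 kb, Mtss1 from 27.4 to 11.2 kb, A1cf, a cofactor of messenger RNA editing, from 18.97 to 6.38 kb, Sult2a8, a sulfotransferase, from 13.7 to 0.84 kb, and Lifr, the leukaemia inhibitory factor receptor, from 19.4 to 7.40 kb. Among the longest additions, Fyb, an adaptor of immune cells, went from 1.198 to 10.7 kb, Pxn, which encodes paxillin, from 17.0 to 26.2 kb, Myh9, a non-muscle myosin, from 13.7 to 22.7 kb, the fatty acid transporter Cd36 from 2.23 to 10.9 kb, Ahnak from 3.19 to 11.7 kb, and Arhgef2 from 3.82 to 10.6 kb. At Myh9 and Ptprj the H3K4me1 regions also numbered more in YAP, 16 against 7 and 25 against 8.

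H3K4me1 regions differed from weak H3K4me2 regions in where they lay, inside genes 54.4 percentage points above random placements in WT and 50.1 points in YAP. This location was first taken up as a pattern with explanations to weigh and is given by its values only, because the sex-biased genes described below, which drew attention in the results, were taken up in its place. The weakest 10% of H3K4me2 regions lay inside genes for 62.6% in WT and 62.1% in YAP, compared with 93.1% and 89.0% of H3K4me1 regions. Genes that held H3K4me1 carried H3K4me2 at an end for 93.1% in WT and 91.3% in YAP, where genes of matched length did for 66.6% and 67.2%.

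LSD1 was listed on about 2 times as many regions in YAP. A WT list that is only a shorter version of the YAP list would lie mostly within the YAP list, whereas 33.8% of WT regions lay in it. This cannot decide whether depth or threshold made the difference, because the share common to libraries of 1 genotype is unknown. Calls that come and go near a threshold remain open, since WT regions in the highest 25% by score were found in YAP 3.01 times as often as those in the lowest 25%, 55.5% against 18.4%. An effect of YAP on LSD1 is also open, and no list per replicate was at hand to compare it with the difference between livers of 1 genotype. How the replicates were combined into each list is not stated either.

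Genes expressed more in livers of male mice carried less H3K4me2 in YAP livers, at 18 of 19 genes with covered bases (median -0.75), while 7 of 12 female-biased genes carried more (median 0.26). The lists came from general knowledge after values of most members had been seen, with Sult1e1, Cyp4a14 and Nox4 seen and left out, so these medians are no independent evidence; seen values include those of Hsd3b5 (3.72 kb to none listed), Elovl3 (5.49 to 2.72 kb) and Cux2 (2.09 to 6.83 kb). YAP livers that were all female are argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, where YAP bases were 0.913 of WT bases, although livers of mixed sex stay possible and the labels give no sex. Among genes whose values had not been looked at, 8 male-biased genes had a median of -0.36 (percentile 1.26) and 6 female-biased genes -0.20 (percentile 17.2), a difference of 0.16, too small to show that both sets moved apart. Whether this is part of the lower coverage of hepatocyte genes in general cannot be told apart here, since the female-biased median of -0.20 lay between that of hepatocyte identity genes (-0.34) and that of all genes (-0.06).

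H3K4me2 was lost less often at YAP-only LSD1 regions (8.55%) and at those of both genotypes (7.73%) than without LSD1, the opposite of what removal of methyl groups at newly listed LSD1 sites would give. Strong and long H3K4me2 regions are lost less often wherever they lie, and this took the loss from 27.3% without LSD1 to 10.0% in sets matched on length and signal, so it may account for most of the difference. The observed 8.55% stood at percentile 0.74 of those sets. Whether length and signal account for all of the difference cannot be told, because the sets were matched on deciles only and not on location. LSD1 and H3K4me2 listings that rise and fall together in a genotype, through open chromatin or through the libraries, remain open, because the ratio of H3K4me2 bases in YAP over WT within 1 kb of LSD1 was 1.11 times as high at YAP-only regions (0.989) as at WT-only regions (0.893). Region lists record presence, so a partial loss of H3K4me2 inside a region that stayed listed would not be seen.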
